A study of Penaeus japonicus with 16 samples.

How the data were processed

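RNA of 5 tissues of apparently healthy kuruma shrimp (Penaeus japonicus, also called Marsupenaeus japonicus) was hybridised to custom Agilent arrays with a single dye, 1 sample per array. There were 3 arrays of gills, 4 of hemocytes, 3 of hepatopancreas, 3 of lymphoid organ and 3 of muscle, 16 in all, on 2 slides of 8 arrays. Groups and replicate numbers were taken from the sample labels. The hepatopancreas arrays carry the numbers 1, 3 and 4 there. Nothing in the labels says that the arrays of a tissue came from separate animals, so the p-values measure the spread between these samples, which may in part be technical.

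The authors deposited 1 table of linear fluorescence intensity, the processed signal of Agilent Feature Extraction, with a flag for every spot (detected, not detected or compromised), and 1 table of log2 values. Feature Extraction was version 10.7.3.1, per the submitters' processing notes. The background subtraction behind the processed intensity is not given in the sources used here. The deposited log2 table equals log2 of the processed intensity minus 1 constant per array, with a spread of that difference of at most 2.94e-06. The constant lies at the 75th percentile of the array, so the scale is log2, the centring is per array, and no centring per gene was found. The median of the deposited log2 column was -2.06, -2.51 and -2.40 for gills 1 to 3 and -2.34, -2.70, -2.52 and -2.64 for hemocytes 1 to 4. It was -2.02, -2.15 and -2.36 for hepatopancreas 1, 3 and 4, -2.24, -2.19 and -2.06 for lymphoid organ 1 to 3, and -2.23, -2.49 and -2.66 for muscle 1 to 3. Why the submitters chose this centring is not given in the sources used here.

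The intensity table held 13935 probes, of which 60 were controls and were left out. The other 13875 comprised 13310 shrimp transcript probes, 526 probes named as genes of white spot syndrome virus and 39 probes for open reading frames of clones. Of the shrimp probes 13076 carried a description and 234 did not, and no 2 of them shared a cluster number, so no probes were averaged. Descriptions are those of the array design and are often the name of a related sequence in another organism. No genome position of the probes is given, because a reference genome was not used here. Compromised values (187) were set to missing.

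Each array's log2 processed intensity was reduced by its own 75th percentile over the 13875 probes. A probe was tested if it was above background, by the deposited flags, on every array of at least 1 tissue, which left 10317 probes, 9988 of them named. One limma model (version 3.58.1, R 4.3.3) with a mean per tissue and moderated variances was fitted to all 16 arrays, with 11 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. A probe was called at an adjusted p under 0.05 and a difference of at least 2-fold. Adjusted p-values of probes are from this limma fit. A probe was tissue-enriched when it was called higher in that tissue than in each of the 4 others, and gill-depleted when called lower in gills than in each other tissue. Errors of fold changes are the model's standard errors (SE), and those of levels are standard deviations (SD).

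Where a probe was above background on no array of the dimmer tissue, its fold is given as a lower bound. The bound sets the bright tissue's mean against the dim tissue's mean of, per array, the higher of the lowest signal among probes above background and the probe's own signal. Differences from the mean of the 4 other tissues use measured signals throughout and are not bounds. A probe's level is log2 intensity minus the array's 75th percentile, so that 0 is that percentile.

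The gene lists, 17 in number, were defined by words in the descriptions before the data were examined, as were the tests, the named-gene rule and most of the alternatives. They cover C-type lectins, other pattern recognition proteins, antimicrobial peptides, the prophenoloxidase cascade with its inhibitors, clotting proteins with hemocyanin, hemocyte markers, contractile muscle proteins, digestive enzymes, ion transport, cuticle and chitin, lysosomal proteins, iron and antioxidant proteins, heat shock proteins, ribosomal proteins, respiratory chain, glycolysis and viral probes. False matches (such as choline transporters among the lectins, unconventional myosins among the muscle proteins, or intracellular and lysosomal hydrolases among the digestive enzymes) were removed by reading the descriptions, before any tissue was compared. The viral list was then set to the 526 viral probes. Each list was tested in each tissue against the equal-weight mean of the 4 others with limma's camera at a preset correlation of 0.01, adjusted over all 85 pairs of list and tissue. The same pairs were tested with an estimated correlation and with fry, which asks whether members move one way on balance.

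Named probes follow a rule fixed in advance, 1 probe per description, the brightest. It takes the 12 gill-enriched probes with the largest smallest difference from the other tissues, up to 6 gill-depleted probes, 6 per other tissue, up to 10 C-type lectins called for gills, up to 3 members each way for each list and tissue described, and 3 each way per gill contrast. For the C-type lectins and list members, probes that share a description were kept apart by cluster number, a departure from the rule's wording made so that family members are not merged. Probes named by another route are said to have been chosen after their values were seen.

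The calculations were tested on simulated data made from these arrays' means and spread. At a difference of 4 log2 units, 88% of changed probes were recovered for gills versus hemocytes, 86% for hepatopancreas, 92% for lymphoid organ and 90% for muscle. At 2 log2 units these were 20%, 18%, 14% and 6%, and at 1 log2 unit at most 2%. Between 4 and 7 unchanged probes of the 10317 were called. For enrichment in gills, 86% were recovered at 4 log2 units and 2% at 2. A list raised by 1 log2 unit was called, and no other list was. The simulated probes varied independently of one another. The simulation therefore does not test list calls where the members of a list vary together. For single probes, most changes of 4-fold or less were missed in the simulated data. Only 50 probes were changed at each size, whereas between 936 and 3467 were called in the real gill comparisons. With so few changed probes the adjustment of p-values is stricter. The simulated shares are therefore not the recovery to be expected in the real comparisons.

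Between 41.0% (muscle 3) and 82.3% (lymphoid organ 1) of the 13875 probes were above background on an array, and the number of arrays limits the precision of each value. Slide was tested as a block and each slide was also fitted alone, where a tissue with a single array is assumed to vary like the others. Such tissues were gills (gills 1) and hepatopancreas (hepatopancreas 1) on slide 1. On slide 2 they were lymphoid organ (lymphoid organ 3) and muscle (muscle 3). Other alternatives were quantile and median normalisation, the deposited log2 table, other probe filters, the replicate number as a block, trended robust moderation, other fold minimums, fits of the compared tissues alone, and leaving out each array in turn. Added after the data were seen were a 75th percentile over the 3312 probes above background on all arrays, and a fit without the 3 arrays (hemocytes 1, hepatopancreas 1 and muscle 3) with under 50% of probes above background. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).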

Results

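Transcript levels were measured in 5 tissues of apparently healthy kuruma shrimp. These were gills (n = 3), hemocytes, the circulating blood cells (n = 4), hepatopancreas, the digestive gland (n = 3), lymphoid organ, a filtering organ of penaeid shrimp (n = 3), and muscle (n = 3). No animal was treated, so every comparison is between tissues, and the series title puts the focus on C-type lectins of the gills. Between 41.0% and 82.3% of the 13875 probes were above background on an array. On slide 1, gills 1 and hepatopancreas 1 were the only arrays of their tissues. Every gill result within slide 1 therefore rests on 1 gill array. On slide 2, lymphoid organ 3 and muscle 3 were the only arrays of theirs. Across probes, which are not independent replicates, arrays of a tissue correlated at r = 0.837 to 0.957 and arrays of different tissues at r = 0.292 to 0.828. The lowest of the latter values was from a hemocyte and a hepatopancreas array, and the highest from a gill and a lymphoid organ array.

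The first comparison asked which C-type lectins, proteins that bind carbohydrates and take part in recognising microbes, gills express. A C-type lectin (cluster014911) had the largest gill difference of the family, with a level of 7.58 ± 0.58 (SD, n = 3; log2 intensity relative to the array's 75th percentile). Its gill arrays lay between 7.11 and 8.23, and no array of another tissue exceeded -2.99. It was at least 3137-fold higher than in hemocytes, 3476-fold higher than in lymphoid organ and 1114-fold higher than in muscle, where no array measured it above background (adjusted p = 5.15e-09, 5.49e-08 and 2.2e-08). Against hepatopancreas, where 1 of 3 arrays was above background, it was 2255-fold higher (log2 difference 11.14 ± 0.69 SE, adjusted p = 3.41e-08). Over the mean of the other tissues its log2 difference was 12.21 ± 0.54 (SE), and it was 12.33 with slide as a block, 12.61 within slide 1 and 12.07 within slide 2. No probe description used here ties it, or any other probe, to the lectin of the series title.

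A further 3 C-type lectin probes were called higher in gills than in each other tissue. The level of c-type lectin 4 (cluster035786) was 2.11 ± 2.21 (SD, n = 3), at least 70.9-fold above hemocytes, 36.3-fold above hepatopancreas and 78.5-fold above lymphoid organ. It exceeded muscle, where 2 of 3 arrays were above background, by 3.98 ± 1.08 log2 units (SE, adjusted p = 0.0122), although its lowest gill array (-0.12) stood close to its highest array elsewhere (-0.33). A C-type lectin (cluster003040) reached 1.76 ± 1.23, at least 55.4-fold above hemocytes and 19.7-fold above muscle. It exceeded hepatopancreas and lymphoid organ by 5.22 ± 0.69 and 5.48 ± 0.69 log2 units (SE). Another (cluster030950) reached 3.60 ± 0.85 and exceeded hemocytes by 7.24 ± 0.72, hepatopancreas by 3.31 ± 0.77, lymphoid organ by 3.51 ± 0.77 and muscle by 6.07 ± 0.77 log2 units (SE). The largest of its 4 adjusted p-values was 0.0085. Within slide 1 alone, c-type lectin 4 (4.61, adjusted p = 0.109) and cluster030950 (4.27, 0.0822) were not called over the mean of the other tissues.

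**Figure D1:**
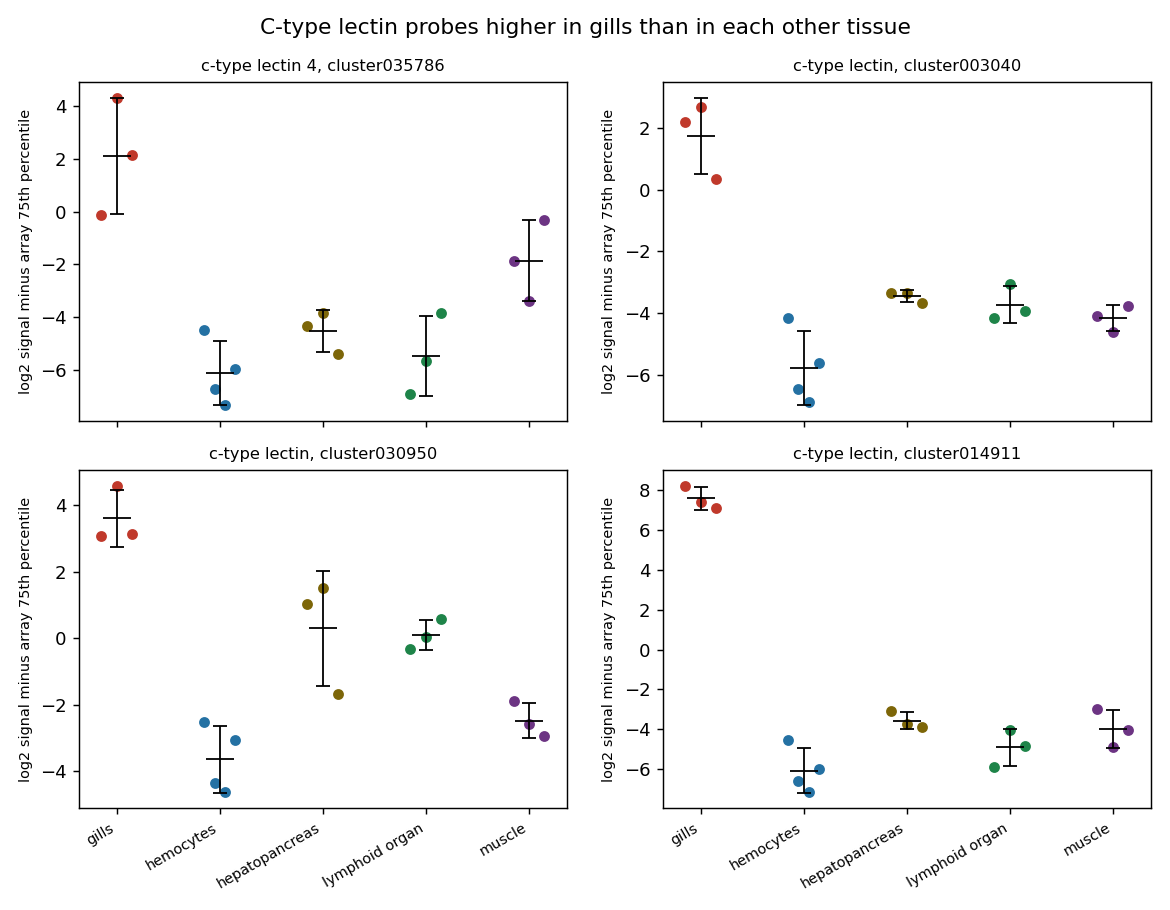
Levels of the 4 gill-enriched C-type lectin probes on each array (points) of each tissue, with the mean and SD, as log2 intensity minus the array's 75th percentile. For cluster014911 the 3 gill arrays lie between 7.11 and 8.23, and every array of the other tissues is at or below -2.99.

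Over the family, more C-type lectin probes were lower than higher in gills against the mean of the other tissues. By number of calls this rests mainly on hepatopancreas, since more were called higher than lower against hemocytes and muscle. Of 56 probes tested (62 on the array), 9 were higher in gills than the mean of the other tissues, 28 were lower and 19 were not called. Adjusted over the list alone, 10 were higher and 34 lower. The lower members were led by cluster020731 (log2 difference -5.09 ± 0.97 SE), cluster031259 (-5.02 ± 0.79), cluster023063 (-4.66 ± 0.90), cluster003996 (-4.60 ± 0.76), cluster019492 (-4.59 ± 0.80) and cluster006771 (-4.42 ± 0.56). Each had a hepatopancreas level between 6.27 and 9.43. In gills cluster031259 and cluster006771 were above background on 0 of 3 arrays, and cluster020731 and cluster019492 on 1 of 3. The gill levels of these probes lie near background, so the sizes of their differences are uncertain. The other named probes, cluster023063 and cluster003996, were above background on all 3 gill arrays. Some of the lower probes were above background on hepatopancreas arrays only. In hepatopancreas 32 of the 56 probes were enriched, against 4 in gills, 3 in lymphoid organ and 1 each in hemocytes and muscle. Gills were higher and lower than hemocytes for 12 and 5 probes, than hepatopancreas for 9 and 33, than lymphoid organ for 5 and 10, and than muscle for 10 and 5. In that order the family medians were -0.05, -5.88, -1.89 and -1.38, so the median was lower in gills than in muscle too. Of the 10 lower than in lymphoid organ 7 were hepatopancreas-enriched, and their lymphoid organ level differed from hepatopancreas by a median of -8.70. The family was lower in gills by camera (median log2 difference -2.28, adjusted p = 0.000965; adjusted p = 0.762 with an estimated correlation and 0.143 with fry). It was higher in hepatopancreas, for 34 probes against 10 lower (34 and 11 adjusted over the list alone; median 5.56, adjusted p = 1.05e-09; adjusted p = 0.548 with an estimated correlation).

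With slide as a block, 8 C-type lectin probes were higher and 26 lower in gills, and the family median was -2.16. Within slide 1 these values were 2, 0 and -1.20 (12 lower in limma at an unadjusted p under 0.05), none of the 6 lower probes named above being called there (log2 differences -3.82 to -2.13). Within slide 2 they were 7, 21 and -2.75, where a tissue with 1 array shares the others' spread. On slide 1 gills and hepatopancreas had a single array each, gills 1 and hepatopancreas 1. Without gills 2, 16 probes in place of 28 were lower.

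Gill-enriched transcripts, higher in gills than in each of the 4 other tissues, numbered 299 of 10317 tested probes under 254 descriptions. Of these, 44 were above background on no array of any other tissue. First was complement c1q-like protein 4-like, named after the C1q family of secreted recognition proteins, at 10.56 ± 0.82 (SD, n = 3). It exceeded its nearest tissue, hepatopancreas, by 11.81 ± 0.98 log2 units (SE, adjusted p = 2.96e-07). Clotting factor b-like, named after a serine protease of horseshoe crab clotting, exceeded lymphoid organ by 10.50 ± 0.95 (SE, adjusted p = 4.54e-06). Its gill level was 7.52 ± 1.63 (SD, n = 2), since the spot on gills 2 was compromised. Keratin-associated protein 10-9-like isoform 2 reached 9.48 ± 1.15 (SD, n = 3), 8.81 ± 0.86 (SE) above hepatopancreas.

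Other named members were below background on every array of muscle, and their bounds are given over that tissue. Chorion peroxidase (gill level 3.38 ± 0.25, SD, n = 3) was at least 60.4-fold higher, a-kinase anchor (4.65 ± 1.09) at least 146-fold, and cg1136 (2.46 ± 0.71) at least 32.0-fold. Alpha-2-macroglobulin-like protein 1, of a family of protease inhibitors (3.11 ± 1.33), was at least 50.1-fold higher, and suppression of tumorigenicity 14, a membrane serine protease (2.92 ± 1.27), at least 44.1-fold. The adjusted p of these 5 was at most 5.58e-05 against any tissue. The remaining 4 of the 12 probes named by the rule carried only hypothetical or predicted descriptions. There were 287 gill-enriched probes with slide as a block, 35 within slide 1 and 74 within slide 2, where a tissue with 1 array shares the others' spread. Complement c1q-like protein 4-like was called in all of these, by 11.81, 12.71 and 11.36 log2 units, whereas a-kinase anchor (5.52, adjusted p = 0.115), alpha-2-macroglobulin-like protein 1 (6.29, 0.0987) and suppression of tumorigenicity 14 (4.72, 0.065) were not called within slide 1.

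**Figure D2:**
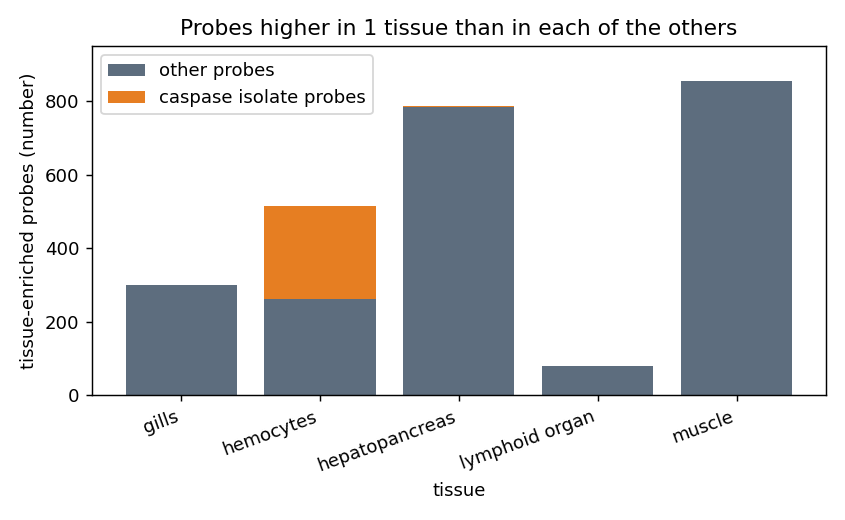
Bars give the number of probes higher in a tissue than in each of the 4 others, 299 in gills, 515 in hemocytes, 788 in hepatopancreas, 81 in lymphoid organ and 854 in muscle. The orange part marks probes for caspase isolates, 252 of the 515 in hemocytes.

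Gill-depleted transcripts, lower in gills than in each other tissue, were 2. Kazal-type serine proteinase inhibitor 4 had a level of -3.39 ± 1.92 (SD, n = 3) in gills against a mean of 9.26 in hepatopancreas, and its smallest difference was -2.78 ± 0.95 log2 units (SE, adjusted p = 0.0376) from muscle. A caspase-like probe, named after its values were seen, had a level of -4.99 in gills, and its smallest difference was -2.21 from muscle (largest adjusted p 0.0183). The call of the Kazal inhibitor was lost with slide as a block (smallest difference -2.53, adjusted p = 0.0605), within slide 1 (-1.86, 0.370), within slide 2 (-1.38, 0.593), and when the percentile was taken over probes above background on all arrays (-2.30, 0.0948). It was also lost, with a smaller difference, without gills 2 (-1.67, 0.188), muscle 1 (-2.51, 0.110) or muscle 2 (-2.04, 0.163). The difference stayed nearly as large without lymphoid organ 2 (-2.78, 0.0521), lymphoid organ 3 (-2.78, 0.0773) or hemocytes 4 (-2.72, 0.0540), where the adjusted p alone was over the threshold. The count was 2 with slide as a block and 0 within either slide (limma; 3 and 15 at an unadjusted p under 0.05). It was 0 without gills 2 (8 unadjusted) or muscle 2 (20 unadjusted), 1 without muscle 1, muscle 3, lymphoid organ 2, lymphoid organ 3 or hemocytes 4, 4 without hemocytes 3 or hepatopancreas 3, 5 without hepatopancreas 4 and 21 without gills 1.

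Against hemocytes, 1457 probes were higher in gills and 1241 lower, 26.2% of those tested. By measured signal, complement c1q-like protein 4-like stood first on the gill side at 14.74 ± 0.92 log2 units (SE, adjusted p = 2.12e-08). With 1 of 4 hemocyte arrays above background, its order relative to the lower bounds that follow is not settled. Keratin-associated protein 10-9-like isoform 2 was at least 11726-fold higher (6.51e-09) and clotting factor b-like at least 3007-fold (1.06e-07). Lower in gills were collagen alpha-1 chain (-5.51 ± 1.03, adjusted p = 0.000673), ras-related protein rab-27a, named after a GTPase of granule secretion (-5.39 ± 0.59, 5.21e-06), and apolipoprotein d (-5.20 ± 1.42, 0.0115). Of 46 hemocyte marker probes 9 were higher in gills and 21 lower, of 48 prophenoloxidase cascade probes 14 and 21, and of 74 cuticle and chitin probes 31 and 1. Of the 1241 lower probes 263 were for caspase isolates and 978 for other transcripts.

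Slide as a block gave 1480 and 1243, slide 1 alone 633 and 408, and slide 2 alone 885 and 533, where a tissue with 1 array shares the others' spread. The call of apolipoprotein d was lost within slide 1 (-4.86, adjusted p = 0.213), within slide 2 (-4.63, 0.0542) and without gills 3 (-4.20, 0.0701), and that of collagen alpha-1 chain within slide 1 (-5.02, 0.0711). With the percentile taken over the 3312 probes above background on all arrays the counts became 1647 and 878. The higher share thus went from 54.0% to 65.2%, while the median of all probes went from -0.16 to 0.20. With the median of each array they were 1343 and 1537, a higher share of 46.6%, and the median was -0.39.

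Against hepatopancreas, 1704 probes were higher in gills and 1763 lower, 33.6% of those tested and the largest of the 4 gill comparisons. On the gill side complement c1q-like protein 4-like differed by 11.81 ± 0.98 log2 units (SE, adjusted p = 2.96e-07), clotting factor b-like was at least 1539.6-fold higher (3.87e-07), and a hypothetical protein (cluster019052) at least 691-fold (1.68e-07). On the hepatopancreas side stood named lectins. Lectin C was at least 8091-fold higher there than in gills (adjusted p = 4.48e-07), lectin A isoform 3 at least 5464-fold (2.32e-07) and lectin A isoform 4 at least 5242-fold (2e-07). Of 101 digestive enzyme probes 16 were higher in gills and 62 lower, and of 61 lysosomal probes 11 and 34. Prophenoloxidase cascade probes were mostly higher in gills, 36 of 48 against 5 lower, as were hemocyte markers (30 of 46 against 6) and antimicrobial peptides (21 of 39 against 5).

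The block by slide gave 1716 and 1820, slide 1 alone 110 and 339, and slide 2 alone 979 and 1516, where a tissue with 1 array shares the others' spread. Slide 1 alone set 1 gill array against 1 hepatopancreas array. With the percentile over probes above background on all arrays the counts were 1146 and 2076, a higher share of 35.6% in place of 49.1%, and the median of all probes moved from 0.16 to -0.24. Quantile normalisation moved them the other way, to 2183 and 1692 (56.3% higher) and a median of 0.42.

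Against lymphoid organ, 494 probes were higher in gills and 442 lower, 9.07% of those tested and the smallest of the 4 gill comparisons. Complement c1q-like protein 4-like was again first by measured signal (12.83 ± 0.98 log2 units, SE, adjusted p = 6.98e-07). It was followed by hypothetical proteins of cluster019052 (at least 1495-fold, 2.32e-07) and cluster019029 (11.43 ± 0.99, 1.65e-06, with 1 of 3 lymphoid organ arrays above background). Lower in gills were heme-binding protein 2 (-7.56 ± 0.81, adjusted p = 1.49e-05), creatinase (-6.61 ± 1.34, 0.00476) and solute carrier organic anion transporter family member 5a1-like (-6.09 ± 1.20, 0.00388). Of 61 lysosomal probes 1 was higher and 12 lower, and of 101 digestive enzyme probes 8 and 16. Hepatopancreas-enriched were 11 of the 16 digestive and 2 of the 12 lysosomal probes, and 70 of all 442 lower probes. Over these 70 the lymphoid organ level differed from hepatopancreas by a median of -8.52, near the -9.13, -8.86 and -8.09 of the brightest 79 hepatopancreas-enriched probes on the lymphoid organ arrays. Hemocyte markers differed for 5 higher and 1 lower of 46, and prophenoloxidase cascade probes for 10 and 1 of 48.

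Slide as a block left 469 and 381, whereas slide 1 alone gave 52 and 6 and slide 2 alone 99 and 17, where a tissue with 1 array shares the others' spread. Creatinase (-5.95 and -5.75, adjusted p = 0.187 and 0.134) and the 5a1-like transporter (-6.76 and -3.73, 0.133 and 0.151) were called within neither slide, and heme-binding protein 2 was not called within slide 1 (-6.96, 0.0766). The transporter was at 0.0525 when only gills and lymphoid organ arrays were fitted. The lower count was 969 without gills 1, 168 without gills 2, and 251, 229 and 291 without lymphoid organ 1, 2 and 3.

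Against muscle, 1437 probes were higher in gills and 1490 lower, 28.4% of those tested. Muscle-specific protein isoform b differed by -13.44 ± 1.25 log2 units (SE, adjusted p = 1.39e-06), pyruvate kinase, the last enzyme of glycolysis, by -12.19 ± 0.66 (1.39e-08), and projectin short variant, a giant muscle filament protein, by -11.46 ± 1.14 (2.93e-06). Higher in gills were complement c1q-like protein 4-like (14.19 ± 0.98, 1.06e-07), keratin-associated protein 10-9-like isoform 2 (11.71 ± 0.86, 1.55e-07) and clotting factor b-like (11.24 ± 0.95, 9.93e-07), each above background on 1 of 3 muscle arrays. Of 88 ribosomal protein probes 3 were higher in gills and 70 lower, of 89 respiratory chain probes 3 and 37, and of 14 glycolysis probes 1 and 7. Antimicrobial peptides were higher in gills for 15 of 39 and lower for 0, and prophenoloxidase cascade probes for 33 and 2 of 48. Hemocyte markers, which share 18 and 15 probes with these lists, were higher for 22 of 46 and lower for 2.

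Blocking by slide gave 1381 and 1407, slide 1 alone 352 and 225, and slide 2 alone 273 and 282, where a tissue with 1 array shares the others' spread. With the percentile over probes above background on all arrays they were 1988 and 940, a higher share of 67.9% in place of 49.1%, and the median of all probes moved from -0.19 to 0.29. The median of each array gave the opposite move, to 1283 and 1688 (43.2% higher) and a median of -0.32. Ribosomal probes lower in gills were 6 with quantile normalisation, 35 with the percentile over probes above background on all arrays and 77 with the median of each array, and respiratory chain probes 25, 22 and 39.

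The gene lists were then compared between gills and the mean of the 4 other tissues, to ask which processes set gills apart. Of 48 prophenoloxidase cascade probes, which cover melanisation and its protease inhibitors, 19 were higher and 2 lower (21 and 3 adjusted over the list alone). More were higher than lower against hepatopancreas (36 and 5), muscle (33 and 2) and lymphoid organ (10 and 1, median 0.003). Against hemocytes fewer were higher than lower (14 and 21). Against the mean of the others the list's median log2 difference was 1.00 (adjusted p = 1.54e-08 with camera, and 0.548 with an estimated correlation). Its members included alpha 2-macroglobulin (cluster015598), at 8.56 ± 0.49 (SE) and above background on no array outside gills, and serine proteinase inhibitor (cluster030171) at 5.93 ± 0.52. Of 39 antimicrobial peptide probes 9 were higher and 4 lower (10 and 5 adjusted over the list alone), with a median of 0.98 (adjusted p = 0.00284; adjusted p = 0.614 with an estimated correlation). These peptides were higher and lower in gills for 21 and 5 against hepatopancreas (median 3.94) and 15 and 0 against muscle (2.80). They were so for 8 and 5 against lymphoid organ (0.32), and for 9 and 7 against hemocytes, where the median was -0.39. Over the mean of the others crustin p, named after cysteine-rich antibacterial peptides of crustaceans, rose by 7.79 ± 0.77 (cluster014337), 7.23 ± 0.94 (cluster033155) and 6.37 ± 0.79 (cluster008964). Lysozyme (cluster027305) was at -5.34 ± 1.18 (adjusted p = 0.00476, and -4.21 with 0.0570 without gills 2). Of 46 hemocyte markers, which share 18 probes with the antimicrobial peptides and 15 with the prophenoloxidase cascade, 9 were higher and 2 lower (11 and 4 adjusted over the list alone). Their median was 0.85 (adjusted p = 0.00059 with camera, and 0.548 with an estimated correlation). The markers were higher and lower in gills for 30 and 6 against hepatopancreas, 22 and 2 against muscle and 5 and 1 against lymphoid organ. Against hemocytes they were higher for 9 and lower for 21 (median -2.79).

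Lists of stress proteins and ion transport were also higher. Of 74 iron and antioxidant probes 16 were higher and 3 lower (17 and 4 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.000276; adjusted p = 0.548 with an estimated correlation). Selenium-dependent glutathione peroxidase was at 7.12 ± 1.00 and cytosolic copper-zinc superoxide dismutase at 6.31 ± 0.78 (SE). Of 38 heat shock probes 9 were higher and 0 lower, also when adjusted over the list alone. Their median was 0.79 (adjusted p = 0.00176; adjusted p = 0.614 with an estimated correlation and 0.056 with fry), and heat shock protein 67b2 (cluster008836) was at 6.73 ± 0.55. Of 49 ion transport probes 16 were higher and 5 lower (19 and 5 adjusted over the list alone). The median was 0.12 and the mean 0.55 (adjusted p = 0.0102; adjusted p = 0.647 with an estimated correlation), and without gills 1 the median was -0.02. Ammonium transporter rh type b-like (4.91 ± 0.47), rh-like protein (4.82 ± 0.59) and carbonic anhydrase 1 (4.41 ± 0.52), names tied to ammonia and acid-base transport, were its leading members.

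Lower in gills were digestive enzymes, for 44 of 101 probes against 13 higher (50 and 13 adjusted over the list alone), with a median of -1.80 (adjusted p = 0.00039; adjusted p = 0.639 with an estimated correlation). By number of calls this rests mainly on hepatopancreas (16 higher and 62 lower). Gills were higher and lower than hemocytes for 14 and 4 of these probes and than muscle for 18 and 15. The median against muscle was -0.55. Against lymphoid organ gills were higher for 8 and lower for 16, and 11 of those 16 were hepatopancreas-enriched. Chymotrypsin-like protein (cluster014858) was at -5.78 ± 1.05 (SE), while probable chitinase 2-like was at 6.60 ± 0.54. Lysosomal probes were lower for 24 of 61 and higher for 4 (28 and 5 adjusted over the list alone), with a median of -1.25 (adjusted p = 0.000145; adjusted p = 0.548 with an estimated correlation). Against hemocytes they were higher and lower for 4 and 5, and against muscle for 8 and 9. The lower calls came from hepatopancreas (11 higher and 34 lower) and lymphoid organ (1 and 12, of which 2 of the 12 were hepatopancreas-enriched). Lysosomal aspartic protease was at -4.98 ± 1.04 and cathepsin c (cluster000858) at -4.39 ± 0.63, against gamma-interferon-inducible lysosomal thiol reductase at 7.72 ± 0.49. Of 88 ribosomal protein probes 2 were lower and 0 higher, also adjusted over the list alone. Their median was -0.47 (adjusted p = 0.000486; adjusted p = 0.83 with an estimated correlation and 0.053 with fry), but 0.13 with quantile normalisation (0.191). Against hemocytes, hepatopancreas and lymphoid organ 3, 2 and 2 were lower, against 70 for muscle. Of 97 white spot syndrome virus probes tested 7 were lower and 0 higher (2 and 0 adjusted over the list alone), with a median of -1.05 (adjusted p = 6.69e-05; adjusted p = 0.762 with an estimated correlation and 0.145 with fry). Gills were lower than hepatopancreas for 43 of these and than muscle for 28, but higher than hemocytes for 7 and lower for 2. This call was lost without gills 2, with a median of -0.48 (adjusted p = 0.215). Of all 10317 tested probes 953 were higher and 871 lower, so 7 of 97 lower is no larger share. Between 9.32% and 26.2% of all 526 viral probes were above background on an array. The subtracted 75th percentile was 5.75, 8.05 and 7.42 on gills 1 to 3. It was 5.09, 5.27 and 6.97 on hepatopancreas 1, 3 and 4, and 5.08, 6.01 and 5.59 on muscle. Probes near background are placed lower where it is higher. How much of the viral differences this makes was not tested.

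The remaining lists were not called in gills. Of 74 cuticle and chitin probes 16 were higher and 6 lower (20 and 6 adjusted over the list alone), and arthrodial cuticle protein (8.84 ± 1.03) and mucin-like peritrophin (-5.16 ± 0.71) were among them. The median of -0.10 and the mean of 0.48 differed in sign, the test was upward (adjusted p = 0.07), and the median was 0.06 with quantile normalisation and 0.03 with the percentile over probes above background on all arrays. That test passed with slide as a block (adjusted p = 0.0372), without gills 2 (0.0101), gills 3 (0.0178), hemocytes 1 (0.0167), hepatopancreas 1 (0.0416), lymphoid organ 3 (0.0403) or muscle 3 (0.0331). Clotting proteins with hemocyanin gave 7 higher and 14 lower of 32, the same adjusted over the list alone, with clottable protein at 5.75 ± 0.52 and hemocyanin (cluster030425) at -4.68 ± 0.93. Their test was upward (adjusted p = 0.932) against a median of -0.23 and a mean of -0.32. Other recognition proteins gave 5 higher and 4 lower of 37 (5 and 7 adjusted over the list alone), with fibrinogen c domain-containing protein 1-like at 6.48 ± 0.77. Their median was -0.10 (adjusted p = 0.949), and 0.03 with the percentile over probes above background on all arrays (0.923).

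Contractile muscle proteins gave 7 higher and 13 lower of 67 in gills, the same adjusted over the list alone, with sarcoplasmic calcium-binding protein at 6.42 ± 0.46 and actin (cluster028590) at -5.57 ± 0.75. Their median was -0.16 (adjusted p = 0.233, and 0.0234 without gills 3), and 0.22 with quantile normalisation (0.725). Respiratory chain probes gave 1 and 1 of 89, the same adjusted over the list alone, with a median of -0.08 and a mean of 0.02 (adjusted p = 0.768). Their median was 0.26 with quantile normalisation (0.0318) and 0.05 with the percentile over probes above background on all arrays. Glycolysis gave 1 and 3 of 14 (1 and 4 adjusted over the list alone; median -0.66, adjusted p = 0.483), with fructose bisphosphate aldolase (cluster009293) at 4.38 ± 0.49.

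By slide, in the order block, slide 1 and slide 2 (where a tissue with 1 array shares the others' spread), the gill medians were 1.12, 0.99 and 1.66 for the prophenoloxidase cascade. They were 1.01, 1.24 and 0.46 for antimicrobial peptides, 1.02, 0.78 and 0.96 for hemocyte markers, 0.34, 0.59 and 0.22 for iron and antioxidant proteins, and 0.50, 0.73 and 0.57 for heat shock. Ion transport gave 0.19, 0.61 and 0.15, digestive enzymes -1.71, -0.81 and -2.37, and lysosomal proteins -1.21, -0.64 and -1.67. Ribosomal proteins gave -0.47, -0.11 (adjusted p = 0.221) and -0.70, viral probes -0.88, 0.45 (0.116) and -1.75, and cuticle and chitin -0.18, 1.12 (0.00015) and -0.82 (0.756). Contractile proteins gave -0.22, -0.71 (0.000289) and 0.09, clotting with hemocyanin -0.12, -0.02 and -0.46, other recognition -0.12, 0.08 and -0.40, the respiratory chain -0.06, 0.30 and -0.36, and glycolysis -0.60, -0.73 and -0.31.

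Across all 85 pairs of list and tissue, 47 passed with camera at its preset correlation, 41 with fry and 0 with an estimated correlation (5 at an unadjusted p under 0.05). Redrawn tissue labels gave as many passing pairs in 5 of 100 draws, the real labels included. The redrawn labels passed 13 to 49 of the 85 pairs. A camera call at the preset correlation is therefore common with labels given at random.

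**Figure D3:**
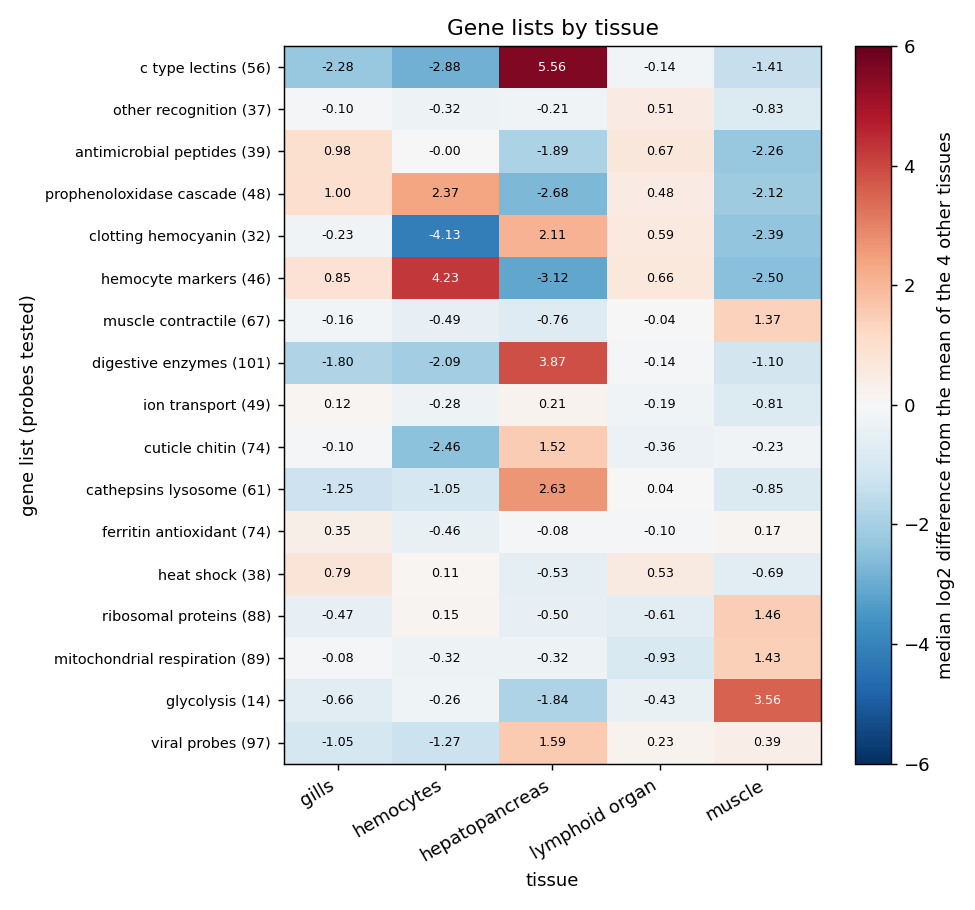
Colour and number give the median log2 difference of each gene list (tested probes in brackets) between a tissue and the mean of the 4 others. C-type lectins (5.56) and digestive enzymes (3.87) stand highest in hepatopancreas, hemocyte markers in hemocytes (4.23) and glycolysis in muscle (3.56), and ribosomal proteins in gills (-0.47) and lymphoid organ (-0.61) turn to 0.13 with quantile normalisation.

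Hemocytes had 515 enriched probes, 252 of them for caspase isolates, leaving 263. The protease inhibitor alpha 2-macroglobulin (cluster015650) had a level of 11.02 ± 0.47 (SD, n = 4) and exceeded lymphoid organ by 4.49 ± 0.58 log2 units (SE, adjusted p = 0.000101), and alpha2-macroglobulin homolog by 4.55 ± 0.71 (0.000415). Fortilin binding protein 1 (4.44 ± 0.65), alpha 2 macroglobulin (cluster015649; 4.33 ± 0.77 above gills) and single vwc domain protein 5 (4.13 ± 0.55) were also named. Fortilin binding protein 1 was called within neither slide (4.61 and 4.30, adjusted p = 0.0557 and 0.0653), alpha2-macroglobulin homolog (3.72, 0.0879) and alpha 2 macroglobulin (cluster015649; 3.45, 0.144) not within slide 1, and single vwc domain protein 5 not within slide 2 (4.11, 0.0513). Apolipoprotein d was nearer the threshold (4.22 ± 1.42, adjusted p = 0.0439). Its call was lost within slide 1 (4.86, 0.213), within slide 2 (2.97, 0.363) and without any of lymphoid organ 1 (3.45, 0.161), hemocytes 1 (3.53, 0.105), hemocytes 2 (3.93, 0.0994), lymphoid organ 3 (4.11, 0.127), hemocytes 3 (4.13, 0.0869), gills 3 (4.20, 0.0701), hepatopancreas 3 (4.22, 0.0560) or muscle 3 (4.22, 0.0545). Hemocyte markers were higher for 27 of 46 probes and lower for 13 (28 and 13 adjusted over the list alone), with a median of 4.23 (adjusted p = 0.000227; adjusted p = 0.548 with an estimated correlation). Hemocyte transglutaminase, a clot cross-linking enzyme, was at 6.39 ± 0.67. Cuticle and chitin probes were lower for 53 of 74 and higher for 0 (59 and 0 adjusted over the list alone), with a median of -2.46 (adjusted p = 7.75e-10; adjusted p = 0.548 with an estimated correlation). Enriched probes numbered 505 with slide as a block, 245 within slide 1, 28 within slide 2, where a tissue with 1 array shares the others' spread, and 340 without lymphoid organ 3. In the same order of slides the marker medians were 4.23, 3.64 and 4.31, and the cuticle medians -2.46, -2.15 and -3.02.

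Hepatopancreas had 788 enriched probes under 559 descriptions. Beta 1-like 2 exceeded its nearest tissue by 9.36 ± 1.01 log2 units (SE), probable chitinase 3-like by 9.13 ± 1.16, lectin E by 9.12 ± 1.39 and carboxypeptidase a2, a protein-digesting enzyme, by 9.09 ± 1.08. That tissue was lymphoid organ in each case, with adjusted p of at most 0.000135. Endoribonuclease-like protein was at least 189-fold above muscle. Of 101 digestive enzyme probes 64 were higher and 10 lower, also adjusted over the list alone (median 3.87, adjusted p = 2.43e-14; adjusted p = 0.548 with an estimated correlation), and chymotrypsin-like protein was at up to 12.05 ± 1.02. Lysosomal probes were higher for 34 of 61 and lower for 18 (34 and 19 adjusted over the list alone), with a median of 2.63 (adjusted p = 2.91e-05; adjusted p = 0.548 with an estimated correlation) and cathepsin d at 11.68 ± 1.05. Clotting proteins with hemocyanin, the oxygen carrier of crustacean blood, were higher for 16 of 32 and lower for 11 (17 and 11 adjusted over the list alone). Their median was 2.11 (adjusted p = 0.00394; adjusted p = 0.665 with an estimated correlation), with hemocyanin (cluster027645) at 11.87 ± 1.12. Slide as a block gave 856 enriched probes, slide 1 307 and slide 2 285, where a tissue with 1 array shares the others' spread, and lectin E was not called within slide 1 (9.05, adjusted p = 0.0715). In that order the digestive medians were 4.21, 4.07 and 4.27, the lysosomal 2.74, 2.55 and 2.76, the C-type lectin medians 5.63, 5.54 and 5.44, and those of clotting and hemocyanin 2.15, 2.07 and 2.23.

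Lymphoid organ had 81 enriched probes under 62 descriptions, the fewest of the 5 tissues. Heme-binding protein 2 exceeded muscle by 5.69 ± 0.81 log2 units (SE, adjusted p = 8.93e-05), and solute carrier organic anion transporter family member 5a1-like exceeded hepatopancreas by 5.21 ± 1.20 (0.00439). Alkaline tissue-nonspecific isozyme-like was at least 9.96-fold and mfs transporter at least 3.57-fold above muscle. Transporter family member 4c1 and fibrinogen c domain-containing protein 1 were above background on no array of another tissue. Other recognition proteins were higher for 10 of 37 probes and lower for 0 (13 and 2 adjusted over the list alone), with a median of 0.51 (adjusted p = 0.00136; adjusted p = 0.548 with an estimated correlation) and fibrinogen-like protein 1-like at 6.06 ± 0.64. Anti-lipopolysaccharide factor (cluster015821), named after peptides that bind bacterial endotoxin, was at 9.18 ± 0.65. The antimicrobial list (9 of 39 higher and 2 lower; 10 and 6 adjusted over the list alone) had an adjusted p of 0.0665, and 0.00978 within slide 2, 0.0241 without lymphoid organ 2 and 0.0316 without gills 3. Respiratory chain probes were lower for 9 of 89 and higher for 0 (29 and 0 adjusted over the list alone), with a median of -0.93 (adjusted p = 1.17e-15; adjusted p = 0.548 with an estimated correlation). With quantile normalisation 2 were lower (median -0.60), and with the median of each array 18 (median -1.14). Enriched probes numbered 81 with slide as a block, 3 within slide 1 and 1 within slide 2, where a tissue with 1 array shares the others' spread, and 53 and 50 without lymphoid organ 1 and 2. None of the 6 probes named above was called within either slide. In the order slide 1 and slide 2, the smallest log2 differences were 6.22 and 4.07 for heme-binding protein 2 (adjusted p = 0.0766 and 0.0591), 3.71 and 3.60 for the alkaline isozyme (0.155 and 0.0628), and 2.78 and 3.74 for fibrinogen c domain-containing protein 1 (0.342 and 0.112). They were 5.48 and 2.87 for transporter 4c1 (0.106 and 0.297), 6.16 and 0.95 for the 5a1-like transporter (0.133 and 0.746), and 2.69 and 2.36 for mfs transporter (0.0637 and 0.471). The recognition medians by slide were 0.54, 0.71 and 0.88, and the respiratory medians -0.95, -0.998 and -0.97.

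Muscle had 854 enriched probes under 765 descriptions. Muscle-specific protein isoform b, at 12.68 ± 0.16 (SD, n = 3), exceeded gills, its nearest tissue, by 13.44 ± 1.25 log2 units (SE, largest adjusted p 2e-06). Pyruvate kinase followed (12.19 ± 0.66), then the contractile proteins troponin i (11.09 ± 1.18), myosin heavy chain type b (10.81 ± 1.66), myosin light chain (10.22 ± 1.14) and myosin heavy chain type a (10.15 ± 1.85). Of 67 contractile probes 33 were higher and 25 lower (34 and 26 adjusted over the list alone), with a median of 1.37 (adjusted p = 0.0138; adjusted p = 0.614 with an estimated correlation). Glycolysis was higher for 8 of 14 and lower for 2, also adjusted over the list alone (median 3.56, adjusted p = 0.000813; adjusted p = 0.548 with an estimated correlation), with enolase at 7.15 ± 0.44. Ribosomal proteins were higher for 80 of 88 and lower for 3 (81 and 3 adjusted over the list alone), with a median of 1.46 (adjusted p = 8.58e-16; adjusted p = 0.548 with an estimated correlation). Respiratory chain probes were higher for 57 of 89 and lower for 3 (61 and 3 adjusted over the list alone), with a median of 1.43 (adjusted p = 1.66e-11; adjusted p = 0.548 with an estimated correlation). Enriched probes numbered 822 with slide as a block, 191 within slide 1 and 65 within slide 2, where a tissue with 1 array shares the others' spread and the myosins (9.71 to 10.91) and muscle-specific protein isoform b (13.09, adjusted p = 0.0635) were not called. By slide the medians were 1.34, 1.37 and 0.85 for contractile proteins, 3.62, 4.04 and 3.09 for glycolysis, 1.45, 1.27 and 1.75 for ribosomal proteins, and 1.45, 1.30 and 1.82 for the respiratory chain. With the percentile over probes above background on all arrays 533 probes were enriched and 41 ribosomal probes were higher (median 0.99), against 13 with quantile normalisation (median 0.59).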

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

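The test against active viral infection was chosen after its result was seen. For genomic DNA, the set of transposable element probes was widened, and agreement of both sets was required, after a first result was seen; the other tests here were set beforehand.

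In hemocytes, single vwc domain protein 5 stood at 10.08 on the array of hemocytes 2, against 8.76 to 8.96 on the other 3 hemocyte arrays. The gap to the nearest array was 0.851 of the whole range, over Dixon's 95% critical value for 4 samples. It was 1 of 16 named probes looked at in this way, and chance gives about 1 in 20.

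Signal was also seen on probes that belong to no shrimp gene list. Of 526 white spot syndrome virus probes 9 were above background on all 16 arrays, although the shrimp were described as apparently healthy. Of 39 probes for open reading frames of clones, all 39 were above background on every lymphoid organ array; what the clones are is not stated. On gills 1, 2 and 3 the numbers of clone probes above background were 37, 6 and 30, on the hepatopancreas arrays 38, 38 and 39, and on the hemocyte arrays between 3 and 12.

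The uneven signal of viral and clone probes between arrays was weighed against an active infection and against genomic DNA in the RNA. The highest share of viral probes above background on any array was 26.2% (lymphoid organ 1), which argues against an active infection with most viral genes transcribed; a low-level or partial infection was not tested. Genomic DNA carried into the RNA stays open, because gills 1 exceeded gills 2 by a median of 5.98 log2 units over the clone probes and the transposable element probes gave different answers by set. The 122 tested ones differed by a median of 4.09 (95% interval 3.04 to 4.67), above the 2.99 set beforehand as the mark for genomic DNA, whereas all 167 had a median of 2.86 (2.08 to 3.30), an interval that spans the mark. Between gills 3 and gills 2 the clone probes differed by 4.31 and the same mark is 2.16. All transposable element probes had a median of 1.34 (1.04 to 1.76), under the mark. The tested ones had 1.79 (1.21 to 2.35), an interval that spans it, so the required agreement fails and this pair of arrays decides nothing either. All shrimp probes had a median of -0.00689 between gills 3 and gills 2. These intervals are taken over probes of a single pair of arrays and hold no spread between samples. On gills 2 only 6 of the 39 clone probes were above background. The subtracted 75th percentile was 8.05 there, against 5.75 on gills 1 and 7.42 on gills 3. Probes near background are thus placed lower on gills 2 by the centring, which enters both the differences and the marks. How much of the differences it makes was not tested. Between gills 1 and gills 2 the medians were 2.85 for the tested viral probes and 0.22 for all shrimp probes. A difference in infection between these samples, which the labels do not tie to separate animals, was not tested.

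Other splits of the same arrays were fitted to see whether chance can be excluded. For gills and hemocytes, 1 of 35 splits, the real one, called as many as 2698 probes, and the highest other split called 1492. Splits that mix the tissues widen the spread and leave few calls. This comparison thus excludes chance only in the sense of arrays grouped at random. For gills with hepatopancreas, lymphoid organ or muscle there are 10 splits each, too few for a share under 0.05. The real values there were 3467, 936 and 2927 probes, each reached by 1 split, and the highest others in limma were 0, 0 and 1. With the tissue labels redrawn 100 times, the real labels included, 1 draw, the real one, reached each of the counts of enriched probes, which were 299 in gills, 515 in hemocytes, 788 in hepatopancreas, 81 in lymphoid organ and 854 in muscle. The same held for the 37 C-type lectin probes called in gills, and the highest other draw in limma was 0 for each. Redrawn labels mix the tissues, which widens the spread and leaves few calls, so these draws exclude chance only in the sense of labels given at random. They decide nothing for the 2 gill-depleted probes, where 1 draw, the real one, reached 2 and the highest other was 0, since the count was also 0 within either slide and 21 without gills 1. For the 47 passing pairs of gene list and tissue chance cannot be excluded. As many were given by 5 of the 100 draws, and the redrawn labels gave 13 to 49.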

How the results depend on the processing

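Alternatives chosen after the data were seen were the 75th percentile over probes above background on all arrays and the fit without the 3 arrays with under 50% of probes above background. Quantile normalisation, slide as a block, fits of the compared tissues alone, the median of each array, the deposited log2 table, all probes, trended robust moderation, no fold minimum and a 4-fold minimum moved no count of probes by over 1.5 times except as given here. Gill-depleted probes were 4 with the median of each array, 5 with the replicate block, 1 without the arrays with under 50% of probes above background and 0 with the percentile over probes above background on all arrays (limma, 11 unadjusted). Muscle-enriched probes were 532 at a 4-fold minimum and 533 with the percentile over probes above background on all arrays, where 940 probes were lower in gills than in muscle. In these cases the cause was not tested.

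Only probes above background on all 16 arrays leaves fewer probes. Gills then had 185 higher and 369 lower than hemocytes, 548 and 218 than hepatopancreas, 63 and 57 than lymphoid organ, and 321 and 859 than muscle. Enriched probes were 27 in gills, 77 in hemocytes, 66 in hepatopancreas, 15 in lymphoid organ and 516 in muscle, with 0 depleted in gills (limma, 3 unadjusted) and 1 C-type lectin higher and 0 lower (3 of 6 unadjusted). List medians turned to -0.19 for lysosomal proteins in gills, 1.31 and -3.08 and 2.01 for C-type lectins in hemocytes, hepatopancreas and muscle, -2.02 for lysosomal proteins in hepatopancreas, and 1.98, 1.10 and -2.65 for contractile proteins in hemocytes, lymphoid organ and muscle. For lysosomal proteins in gills it was the direction of the test that turned.

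Each slide alone holds fewer samples. Gills and hepatopancreas had a single array each on slide 1, and lymphoid organ and muscle had a single array each on slide 2. Slide 1 only gave 633 and 408 against hemocytes, 110 and 339 against hepatopancreas, 52 and 6 against lymphoid organ, and 352 and 225 against muscle. Its enriched probes were 35 in gills, 245 in hemocytes, 307 in hepatopancreas, 3 in lymphoid organ and 191 in muscle, with 0 depleted (3 unadjusted) and 2 and 0 C-type lectins higher and lower. Slide 2 only gave 885 and 533, 979 and 1516, 99 and 17, and 273 and 282, with 74, 28, 285, 1 and 65 enriched, 0 depleted (15 unadjusted) and 7 and 21 C-type lectins. The median of viral probes in gills turned to 0.45 within slide 1. Only the direction of the test turned for heat shock in lymphoid organ within slide 1 (median 0.50, and 0.53 over both slides) and for viral probes there within slide 2 (1.06, and 0.23 over both slides). Of the named results 91 of 169 lost their call within slide 1 and 46 of 167 within slide 2, none turning in sign. Lost elsewhere were 13 without the arrays with under 50% of probes above background, 9 with the percentile over probes above background on all arrays, 9 at a 4-fold minimum, 7 with all probes, 5 with quantile normalisation, 5 with slide as a block, 4 with the replicate block, 4 with trended robust moderation, 2 of the 29 that could be fitted with the strict filter and 1 of 24 with the compared tissues alone.

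Of the 85 pairs of list and tissue 0 passed with an estimated correlation (5 unadjusted), and the lowest adjusted p was 0.548. With fry 8 calls were lost and 2 gained, with the percentile over probes above background on all arrays 4 and 1, with all probes 1 and 6, and with quantile normalisation 3 and 4. Quantile normalisation also turned ribosomal proteins to 0.13 in gills and 0.13 in lymphoid organ. No general pairing by replicate number was seen. Deviations of arrays with the same number correlated at a mean of 0.0182 (8 of 27 pairs over 0.1) and those with different numbers at -0.00719 (17 of 75). Pairs with the same number ranged from -0.405 to 0.399, so these means cannot exclude that some numbers mark shared animals. The replicate block gave 287 gill-enriched probes and 47 passing pairs.

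Leaving out each array in turn gave 1208 to 1531 higher and 1013 to 1444 lower than hemocytes, 1213 to 1900 and 1282 to 1992 than hepatopancreas, 352 to 542 and 168 to 969 than lymphoid organ, and 1106 to 1562 and 1001 to 1682 than muscle. Enriched probes ranged from 222 to 322 in gills, 340 to 545 in hemocytes, 575 to 892 in hepatopancreas, 50 to 83 in lymphoid organ and 648 to 912 in muscle. Gill-depleted probes ranged from 0 (8 unadjusted without gills 2, 20 without muscle 2) to 21, C-type lectins from 7 to 9 higher and 16 to 31 lower, and list pairs from 44 to 50. Of 169 named results 36 lost their call without some array and 0 turned in sign. Normexp background correction was not run, because the intensities were already processed, and neither was averaging of probes, because no cluster number was shared.

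Whether the 75th percentile, moved by the share of probes above background, accounts for general shifts was tested on a pair of lists. The ribosomal median in muscle went from 1.46 to 0.59 with quantile normalisation (80 to 13 probes higher) and to 0.99 with the percentile over probes above background on all arrays, so the first is in line with this explanation for much of the shift. The respiratory chain median in lymphoid organ went from -0.93 to -0.60 with quantile normalisation (9 to 2 probes lower) and to -0.89 with the other percentile, which argues against it as the whole cause. A difference between the tissues themselves stays open for both. Between 41.0% and 82.3% of probes were above background on an array, which limits what can be said of dim probes.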

Other observations

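The gene groups here, the tests of a trace of hepatopancreas RNA and the test of a neighbouring array were chosen after the values were seen, and the trace was tested again against single hepatopancreas arrays after a first test against their mean had gone with it. Lectins A to F, which are outside the C-type lectin list, were enriched in hepatopancreas for 12 of 12 probes, with a median level of 8.22 there and a median log2 difference of 11.47 from the other tissues. Cytochrome P450 probes, oxidising enzymes of detoxification and hormone synthesis, were higher in hepatopancreas for 28 of 54 and lower in hemocytes for 36. Vitellogenin, the egg yolk precursor, had 5 tested probes, 2 enriched in gills and 3 in hepatopancreas. Of 292 tested caspase probes 279 were higher in hemocytes, with a median level of -0.45 there and -4.95 in gills, but 269 of them are probes for isolates and not separate genes.

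Probes named as transposable elements were higher in hepatopancreas for 77 of 122 and lower in hemocytes for 58. Clone probes were higher in hepatopancreas for 38 of 39 and lower in hemocytes for 36. Solute carriers were lower in hemocytes for 21 of 48, and higher for 7 to 12 in each tissue. Of 7 tested nuclear histone probes 4 were higher in hemocytes.

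The brightest 79 hepatopancreas-enriched probes lay below hepatopancreas on the lymphoid organ arrays by medians of -9.13, -8.86 and -8.09 log2 units. Whether a trace of hepatopancreas RNA in the lymphoid organ samples accounts for this stays open. The differences between a lymphoid organ and a single hepatopancreas array had median absolute deviations of 0.506 to 0.947, which span the 0.576 to 0.667 between hepatopancreas arrays, so how constant the distance is decides nothing. Hemocyanin (cluster027645) was at 11.03 in hepatopancreas and 2.16 in lymphoid organ, and muscle 1 (-8.56) stood apart from muscle 2 (-12.30) and muscle 3 (-11.94). Hemocytes 4 (-10.40, with 77 of the 79 probes above background) stood apart from the other hemocyte arrays (-14.06 to -11.86, with 31 to 47). Signal leaking from a neighbouring array of the slide is argued against, since gills 2 (-14.22) and gills 3 (-12.03), beside hepatopancreas arrays, lay at least 2.90 below the lymphoid organ arrays. Every lymphoid organ array also lay beside a hepatopancreas array, so this rests on gills 2 and gills 3 alone. Of the 79 probes, 44 and 49 were above background on them. Low expression of these genes in the lymphoid organ itself stays open too and was not tested.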
